A study of Mus musculus with 18 samples.

How the data were processed

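The series holds 18 libraries of transfer RNA from CD4 T cells of B6 female mice aged 7 weeks. Per the labels, 6 spleens were pooled 2 at a time into 3 pools; a part of the cells was sorted as naive and the rest was activated with beads carrying antibodies to CD3 and CD28. The 6 groups of 3 libraries are naive cells, live cells at 20 h, and CD62L-high and CD62L-low cells at 48 h and at 72 h. Replicates are named by the number in their titles. Whether equal numbers in different groups mark the same pool is not stated, so the groups were treated as unpaired. The labels name the sort of the naive cells with the same markers as the memory cells, so the exact naive gate is uncertain. The protocol in the labels removes methyl groups from the RNA with the enzyme AlkB and a mutant of it, and copies it with a thermostable group II intron reverse transcriptase. The submitters' processing notes name the mouse build mm10, Bowtie2 and bedtools without versions or roles. How reads matching several tRNAs were assigned is not stated.

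The deposited tables give the values in RPM, reads per 1000000 reads of the cytosolic tRNA table itself, and every column sums to 1000000. The table by tRNA has 279 entries and the table by anticodon 57 families. The deposited score column, with 1 score per tRNA entry and no stated source, was used in a single test of the closing section. Each family equals the sum of its entries, with a largest difference of 7.9e-10 RPM. Columns whose names end in deMe, 4 in each table and 8 in all, match no listed sample and were left out; what their names imply about the methyl treatment of the 18 used columns is uncertain. All 279 values of each column were whole multiples of a step, within 0.01 reads, and the step gave the depth of the library in reads. Too few low values were present to accept the multiples as recovered counts for a count test, so the tests were run on the RPM scale. The depths, the thinning and the chi-square between replicates took the multiples as reads and hold only if they are. Naive replicates 1 to 3 held 491863, 264400 and 759016 reads, the 20 h libraries 697610, 538489 and 1476291, the 48 h CD62L-high libraries 880968, 627567 and 659625, the 48 h CD62L-low libraries 946248, 945266 and 682257, the 72 h CD62L-high libraries 789373, 424043 and 767466, and the 72 h CD62L-low libraries 695286, 344881 and 333101. A listed 0 allows up to 3 reads, which is between 2.03 RPM in 20 h replicate 3 and 11.3 RPM in naive replicate 2. The reads are PCR products without molecular identifiers, so these floors cover counting error only.

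Families and entries with a mean of at least 10 RPM over the 18 libraries were tested, 48 and 148 of them. The rest held 0.00197% and 0.0192% of the reads, and 49 entries were listed at 0 in every library. Values were transformed to log2(RPM + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean for each group, all 18 libraries in the fit and empirical Bayes moderation with a variance trend. A call is a Benjamini-Hochberg adjusted p under 0.05 within the comparison. The 12 comparisons were each activated group against naive cells, 48 h against 20 h, 72 h against 48 h, CD62L-low against CD62L-high over both times and at each time, the difference between those differences, and any difference among the 6 groups. Fold changes are 2 to the power of the fitted log2 change. The p-values measure the spread between these libraries, which come from 3 pools of mice.

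The design, the tests, the lists and the rule for named items were fixed before the data were examined. In each comparison the text names up to 10 families each way with the largest change among those called whose groups did not overlap, or, for averaged comparisons, whose sign was the same in each part, and with a mean of at least 100 RPM. It also names iMet-CAT, Met-CAT, Phe-GAA, Lys-TTT and SeC-TCA in each, up to 5 entries each way by the same rule, up to 4 members of each list, and Arg-TCT-4-1 as a marker of nervous tissue. The 18 lists group families by the first anticodon base (A, read as inosine, or G, C or U), by modification (Elongator-dependent uridines, queuosine, t6A, i6A, m3C), by the long variable arm, by the kind of amino acid (branched-chain, positively charged, negatively charged, small, aromatic, sulfur) and by the ending of the best matched codon (A or U, G or C). Lists were tested in 6 comparisons with camera, at a preset correlation of 0.01 and with an estimated correlation, and with fry, and adjusted over the lists of a comparison. Shares of reads were compared with two-sided exact permutation tests for 3 against 3 libraries, whose smallest p is 0.1, and with a permutation test of the F ratio over the 6 groups with 100000 resamples.

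The alternatives fixed in advance were a pseudocount of 0.1 or 10, no filter or a filter at 100 RPM, TMM factors (trims of 30% and 5%), a shift of each library to the same median, robust moderation, the replicate number as a term, the compared groups alone, and leaving out each library in turn. After the data were seen, a term for the replicate 1 libraries and leaving those 6 libraries out were added. So were thinning all libraries to the lowest depth and summing pairs of entries of 1 anticodon. The 7 summed pairs, of 144 compared, had a within-group r under -0.5. The spread of their log2 sum within groups was under 0.5 of that of their log2 ratio. Tested on simulated data with 12 of 48 families changed, the 20 h comparison called 20% of 1.5-fold, 51.5% of 2-fold and 93.5% of 4-fold changes, with 3.43% false calls, and the comparison of CD62L fractions 45%, 82.5% and 97.5%, with 4.45%. With 36 of 148 entries changed the shares were 8%, 33.5% and 81% (2.59% false) and 27.3%, 62.3% and 93% (3.68% false). A list shifted by 1 on the log2 scale was called in 100% of 50 simulations. All of these simulations drew noise independently for each row and library. In the data 1 component held 54.4% of the residual variance of the families and 35.1% of that of the entries. The simulated rates of recovered and false calls may therefore not hold for these libraries. No pair of replicates was a duplicate: over 18 pairs the chi-square per degree of freedom of their reads lay between 66.6 and 1380. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genome and tRNA sequences were not used here, so positions and sequence identity between entries are not given.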

Results

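Transfer RNA was sequenced from mouse CD4 T cells sorted as naive and from cells stimulated in culture. The stimulus was beads carrying antibodies to CD3 and CD28, which stand in for antigen and costimulation. The 18 libraries form 6 groups of 3: naive cells, cells at 20 h of activation, and cells sorted for high or low surface CD62L at 48 h and at 72 h. CD62L is the lymph node homing receptor; the labels call the CD62L-high, CD44-positive cells memory and the CD62L-low, CD44-positive cells effector. The 20 h cells were sorted only for being alive. Per the labels, the activated cells were the rest of the cells and not the part sorted as naive. No group was cultured without beads. Comparisons with naive cells therefore cannot tell activation apart from time in culture, the sort or the starting cells. Each library held between 264400 reads (naive replicate 2) and 1476291 reads (20 h replicate 3), as worked out from the steps of the deposited values. Values are reads per 1000000 tRNA reads (RPM), so each is a share of the library and not an amount per cell. The deposited tables list 57 anticodon families and 279 individual tRNA entries, named by amino acid, anticodon and a number for the sequence. After a filter at a mean of 10 RPM, 48 families and 148 entries were tested. The Lys-CTT family took the largest mean share of reads over the 18 libraries, 14.9%, followed by Gln-CTG at 8.20%, Glu-CTC at 6.12%, His-GTG at 4.98% and Gly-GCC at 4.70%.

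The comparison of 20 h cells with naive cells asks how the tRNA pool differed early in activation. The serine family Ser-GGA was at 203 ± 138 RPM (SD, n = 3) at 20 h against 8.79 ± 6.56 RPM in naive cells, and the alanine family Ala-TGC at 4481 ± 884 RPM against 2352 ± 60.2 RPM. Both rose, by 4.48 (SE 0.75, adjusted p = 0.000887) and 0.91 (SE 0.22, adjusted p = 0.0183) on the log2(RPM + 1) scale, and these were the 2 families of 48 called; no family was called lower. Ser-GGA has 1 tested entry, and its naive level lies near the RPM of 3 reads (3.95 to 11.3 RPM in the naive libraries), so the size of its change rests on few naive reads. The initiator methionine family iMet-CAT, which starts protein synthesis, was at 42368 ± 6380 RPM against 62219 ± 5852 RPM, a log2 change of -0.56 that did not pass the test (adjusted p = 0.264). Phe-GAA (log2 change 1.06), Met-CAT, the elongator methionine family (-0.47), Lys-TTT (0.33) and the selenocysteine family SeC-TCA (-0.63) did not pass either. Both SeC-TCA (-1.31) and Phe-GAA (1.48, adjusted p = 0.0476) did pass without naive replicate 2, and Lys-TTT was at 1.24 without it (adjusted p = 0.161) and at -0.17 without naive replicate 1. Both iMet-CAT and Phe-GAA passed with a term for the replicate 1 libraries (adjusted p = 0.0415 and 0.0221). The call on Ala-TGC was lost on leaving out naive replicate 1 or 3 or 20 h replicate 1 or 3 (highest adjusted p = 0.152), and under TMM scaling (adjusted p = 0.0658) or a shift of the libraries to 1 median (adjusted p = 0.0649).

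Among individual entries at 20 h, 61 rose and 7 fell of 148. Tyr-GTA-3-1 went from 27.7 ± 12.1 to 1952 ± 520 RPM, Gly-CCC-2-1 from 43.6 ± 36.4 to 979 ± 229 RPM and Lys-TTT-2-1 from 8.0 ± 12.7 to 157 ± 25.8 RPM (n = 3 in each group), log2 changes of 6.14, 4.98 and 5.36. Gly-CCC-3-1 rose by 4.35. In naive cells Lys-TTT-2-1 was listed at 0 in replicate 1 and at 1.32 RPM in replicate 3, both under the RPM of 3 reads, so the size of its change is uncertain in every comparison with naive cells. Leaving out single libraries gave 4.40 to 6.68 for it, 3.99 to 5.69 for Gly-CCC-2-1 and 3.50 to 5.02 for Gly-CCC-3-1. Those that fell included Tyr-GTA-2-1 (-4.71, adjusted p = 0.0200), Gly-GCC-4-1 (-2.55, from 48875 ± 15570 to 8410 ± 2671 RPM, while Gly-GCC-2-1 rose by 3.24 and their family was not called, at 0.19 with adjusted p = 0.897), Ile-TAT-2-1 (-1.06), Gln-TTG-1-1 (-0.89) and Cys-GCA-3-1 (-0.74). The calls on Tyr-GTA-2-1, Ile-TAT-2-1, Gln-TTG-1-1 and Cys-GCA-3-1 were lost without naive replicate 2, with adjusted p = 0.0648, 0.225, 0.174 and 0.242, and over all 18 libraries in turn for 2, 5, 9 and 11 of them. Entries of 1 anticodon can be near-identical in sequence and the handling of reads that match several entries is not given in the sources used here, so every value of a single entry is uncertain in that respect. The sum of Tyr-GTA-2-1 and Tyr-GTA-3-1 changed by -0.23 (adjusted p = 0.693), and that of Gly-CCC-1-1 and Gly-CCC-2-1 by 0.12 (adjusted p = 0.749), so neither pair as a whole was called. Arg-TCT-4-1, a tRNA known for its expression in the nervous system and included as a marker of other cells, stood at 2163 ± 184 RPM in naive cells and 4585 ± 563 RPM at 20 h (log2 change 1.08, adjusted p = 0.0109). That call was lost under TMM scaling (0.52, adjusted p = 0.130) and the median shift (0.45, adjusted p = 0.231), and the 4 later groups gave no call (adjusted p from 0.0645 to 0.557).

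At 48 h the CD62L-high cells differed from naive cells in 4 families, 3 of them higher. Ala-AGC, whose first anticodon base is converted to inosine in the mature tRNA, rose from 5003 ± 1268 to 12444 ± 2271 RPM (2.51-fold, log2 change 1.33, SE 0.25, adjusted p = 0.00401). Ala-TGC rose 1.90-fold (adjusted p = 0.0104) and Ser-GGA by 3.31 (adjusted p = 0.0102). The family iMet-CAT fell by 0.71 on the log2 scale (adjusted p = 0.0463), from 62219 to 38212 ± 4675 RPM. With the compared groups alone no family was called, and fewer were called without the replicate 1 libraries. The iMet-CAT call was lost on leaving out any of 14 of the 18 libraries (highest adjusted p = 0.218); that on Ser-GGA was lost without naive replicate 1 or 48 h CD62L-high replicate 3 (highest adjusted p = 0.0607), and that on Ala-TGC without the latter (adjusted p = 0.0651). Phe-GAA (0.83), Met-CAT (-0.08), Lys-TTT (-0.18) and SeC-TCA (-0.36) did not pass. Without naive replicate 2 SeC-TCA was called (-1.04, adjusted p = 0.0260) and Lys-TTT was at 0.73 (adjusted p = 0.646), and without naive replicate 1 Met-CAT and SeC-TCA were at 0.02 and 0.04. Of the 148 entries 59 rose and 9 fell. The rises included Gly-CCC-2-1 (6.00), Lys-TTT-2-1 (5.75), Thr-CGT-4-1 (5.55, from 15.4 ± 8.91 to 694 ± 141 RPM), Gln-TTG-2-1 (5.52) and Gly-CCC-3-1 (5.07). Without single libraries the change of Gly-CCC-2-1 lay between 5.0 and 6.71, that of Lys-TTT-2-1 between 4.79 and 7.07, that of Gly-CCC-3-1 between 4.23 and 5.74 and that of Gln-TTG-2-1 between 5.03 and 6.22. The falls included Arg-TCG-1-1 (-1.60), Ala-AGC-4-1 (-1.43), Arg-TCT-2-1 (-1.17), Gln-TTG-1-1 (-1.01) and Cys-GCA-3-1 (-0.98). Without naive replicate 2 the calls on Arg-TCG-1-1, Arg-TCT-2-1, Gln-TTG-1-1 and Cys-GCA-3-1 were lost (adjusted p = 0.0514 and 0.108 for the arginine entries and 0.0663 for Cys-GCA-3-1).

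The CD62L-low cells at 48 h differed from naive cells in 6 families. Ala-AGC reached 16329 ± 3616 RPM (3.27-fold, log2 change 1.71, adjusted p = 0.000226), Ala-TGC 5068 ± 1078 RPM (2.12-fold, adjusted p = 0.00237) and Ser-GGA 166 ± 94.7 RPM (log2 change 4.24, adjusted p = 0.000821). Phe-GAA rose from 1389 ± 771 to 3358 ± 1113 RPM (2.59-fold, adjusted p = 0.0455) and Val-AAC from 2173 ± 333 to 5111 ± 1664 RPM (2.28-fold, adjusted p = 0.0455). The family iMet-CAT fell by 0.79 (adjusted p = 0.0195), to 35912 ± 3140 RPM. Met-CAT (-0.12), Lys-TTT (0.19) and SeC-TCA (-1.10) did not pass, but SeC-TCA passed without naive replicate 2. Lys-TTT was at 1.10 without that library (adjusted p = 0.189) and at -0.31 without naive replicate 1. The calls on Phe-GAA and Val-AAC were each lost on leaving out 1 library, for 11 and 10 of the 18 libraries (highest adjusted p = 0.220 and 0.173), and that on iMet-CAT without naive replicate 3 or 48 h CD62L-low replicate 1 (highest adjusted p = 0.0918). Among entries, 59 rose and 20 fell. Gly-CCC-2-1 reached 3251 ± 654 RPM (log2 change 6.72), Lys-TTT-2-1 400 ± 53.0 RPM (6.71), Gln-TTG-2-1 1372 ± 373 RPM (6.25), Thr-CGT-4-1 1072 ± 492 RPM (6.08) and Tyr-GTA-3-1 1839 ± 884 RPM (5.98). Leaving out single libraries gave 5.75 to 8.03 for Lys-TTT-2-1, 5.72 to 7.43 for Gly-CCC-2-1 and 5.76 to 6.95 for Gln-TTG-2-1. Tyr-GTA-2-1 (-4.91), Gly-GCC-4-1 (-1.91), Arg-TCG-1-1 (-1.76), Gln-TTG-1-1 (-1.46) and Arg-TCT-2-1 (-1.46) fell. Without naive replicate 2 the calls on Tyr-GTA-2-1 and Gly-GCC-4-1 were lost (adjusted p = 0.0510 and 0.0568), the latter also without 48 h CD62L-low replicate 1; its change lay between -2.54 and -0.90 over the libraries left out in turn.

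At 72 h, 3 families were called in the CD62L-high cells against naive cells. Ala-AGC rose to 11638 ± 1880 RPM (2.35-fold, log2 change 1.23, adjusted p = 0.00837). Both methionine families fell, iMet-CAT by 0.89 (to 33692 ± 5738 RPM, adjusted p = 0.0140) and Met-CAT by 0.91 (from 10008 ± 1881 to 5350 ± 1047 RPM, adjusted p = 0.0224). With the compared groups alone, or without the replicate 1 libraries, no family was called. Phe-GAA (-1.05), Lys-TTT (-0.90) and SeC-TCA (0.08) did not pass, Phe-GAA passing after the shift to 1 median (-1.01, adjusted p = 0.0408). Without naive replicate 2 Lys-TTT was at 0.01 and SeC-TCA at -0.60 (adjusted p = 0.342), neither called. Leaving out 72 h CD62L-high replicate 2 ended the calls on iMet-CAT (-0.79, adjusted p = 0.0938) and Met-CAT (-0.74, adjusted p = 0.161); so did naive replicate 3 for iMet-CAT and naive replicate 1 or 2 for Met-CAT. Among entries 49 rose and 13 fell. Ala-AGC-3-1 went from 351 ± 180 to 7062 ± 1712 RPM (log2 change 4.47) and Leu-CAA-4-1 from 173 ± 27.9 to 3299 ± 1028 RPM (4.21), with Gln-TTG-2-1 (4.63), Gly-CCC-2-1 (4.22) and Ala-AGC-1-1 (4.09) also higher. Leaving out single libraries gave 4.14 to 5.33, 3.22 to 4.92 and 3.07 to 4.78 for the last 3. Ile-TAT-2-1 (-1.40), Phe-GAA-1-1 (-1.27), Met-CAT-2-1 (-1.10), Met-CAT-1-1 (-1.03) and Arg-TCG-2-1 (-1.02) fell. The calls on Ile-TAT-2-1, Phe-GAA-1-1 and Arg-TCG-2-1 were lost without 72 h CD62L-high replicate 2 (adjusted p = 0.0607 for Ile-TAT-2-1 and 0.0564 for Arg-TCG-2-1), the first of these and Phe-GAA-1-1 also without naive replicate 2 (adjusted p = 0.0547 and 0.154).

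The CD62L-low cells at 72 h had 4 called families. Ala-AGC was at 16406 ± 2565 RPM (3.32-fold over naive, log2 change 1.73, adjusted p = 0.000196), Val-AAC at 7179 ± 2754 RPM (3.13-fold, adjusted p = 0.00579) and Ser-GGA at 176 ± 132 RPM (log2 change 4.05, adjusted p = 0.00136). Leaving out single libraries gave 3.35 to 4.91 for Ser-GGA. The family iMet-CAT fell by 0.80 (adjusted p = 0.0186), a call lost without naive replicate 3 or 72 h CD62L-low replicate 1 (-0.65, adjusted p = 0.151). Phe-GAA (0.78), Met-CAT (-0.01), Lys-TTT (0.58) and SeC-TCA (-0.43) did not pass. Without naive replicate 2 SeC-TCA was called (-1.11, adjusted p = 0.0155) and Lys-TTT was at 1.49 (adjusted p = 0.0560), and without naive replicate 1 Met-CAT was at 0.10. Of the entries 60 rose and 6 fell. Gln-TTG-2-1 (5.90), Lys-TTT-2-1 (5.60), Val-AAC-4-1 (5.46, from 37.9 ± 23.1 to 1575 ± 407 RPM), Gly-CCC-2-1 (5.30) and Thr-CGT-4-1 (5.23) rose. Tyr-GTA-2-1 (-4.24), Arg-TCG-1-1 (-1.49), Ala-AGC-4-1 (-1.01), iMet-CAT-1-1 (-0.80) and Thr-CGT-1-1 (-0.70) fell. Leaving out single libraries gave 5.41 to 6.6 for Gln-TTG-2-1, 4.64 to 6.92 for Lys-TTT-2-1, 4.30 to 6.00 for Gly-CCC-2-1 and -5.77 to -3.24 for Tyr-GTA-2-1. All of these falls but that of iMet-CAT-1-1 lost their call without 72 h CD62L-low replicate 1 and without naive replicate 2 (highest adjusted p = 0.158, for Thr-CGT-1-1).

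**Figure D1:**
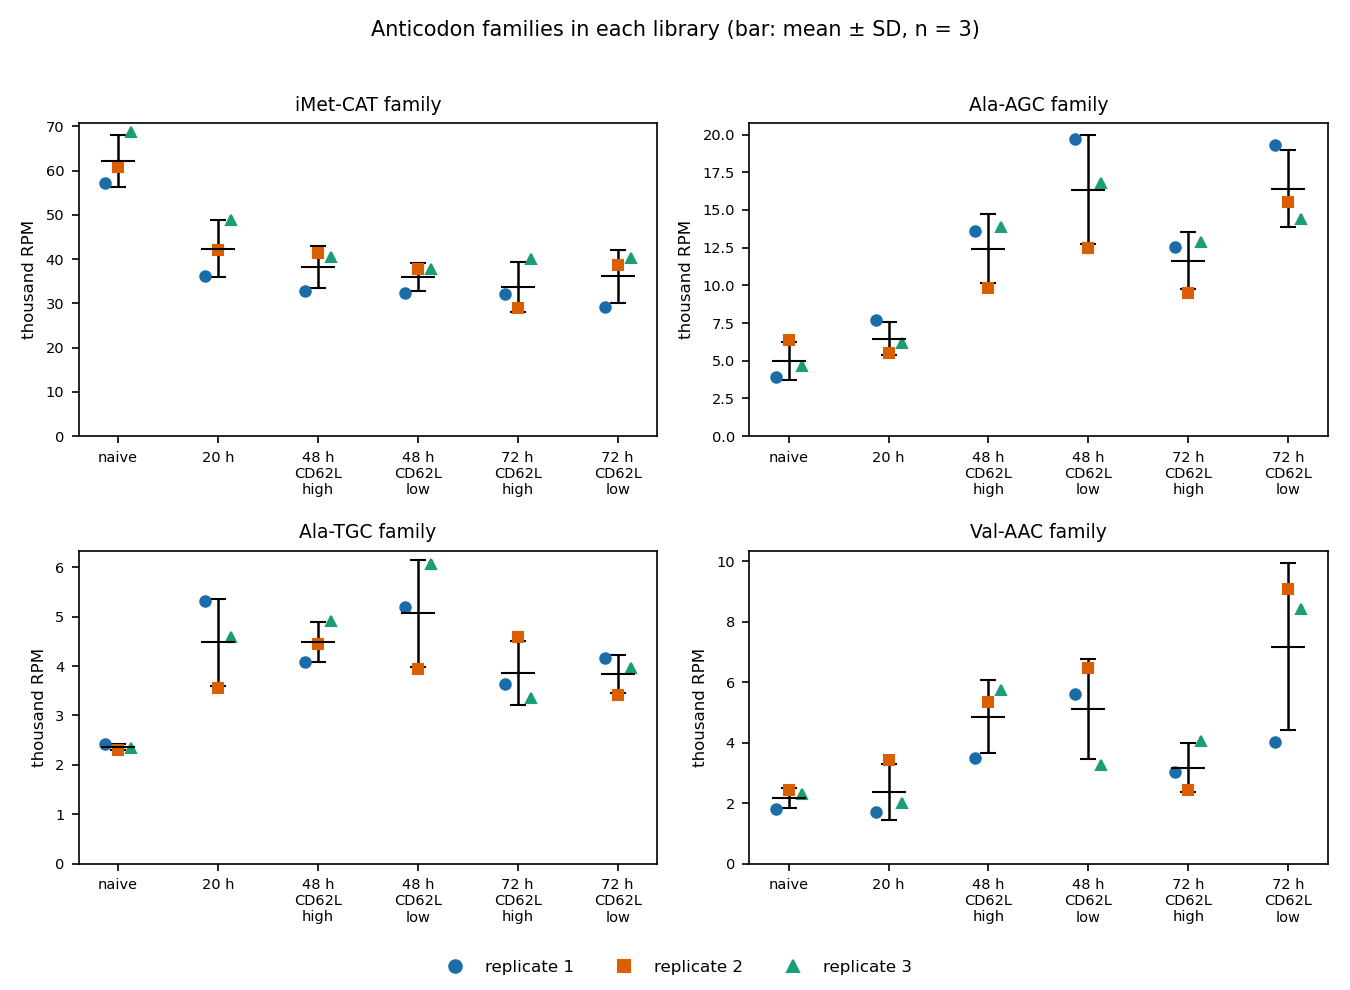
RPM of anticodon families in each of the 18 libraries by group, with points for libraries and lines for group means (n = 3 each). Ala-AGC lies between 11638 and 16406 RPM on average in the sorted 48 h and 72 h groups against 5003 RPM in naive cells, and iMet-CAT between 33692 and 42368 RPM in the activated groups against 62219 RPM.

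Across the 5 comparisons with naive cells, 45 entries from 28 anticodon families were higher in every one and 1, iMet-CAT-1-1, was lower in every one. In 100 simulations of unchanged groups sharing their naive libraries, 0 entries were called in all 5 on average and 0.03 in 2 or more. With so few calls, they do not show how much overlap lists of the real lengths would owe to the shared naive libraries. Independent lists of these lengths would share 1.3 higher entries. With 3 naive libraries the controls could not be split, so the overlap is not independent evidence from 5 comparisons. That iMet-CAT-1-1 is named here was decided after its values were seen. Its family was not called at 20 h (adjusted p = 0.264). The 45 included 4 of Ala-AGC, 3 each of Val-AAC, Gln-CTG and Thr-AGT, and 2 each of Gly-CCC, Arg-TCT, Ala-TGC, Leu-TAG, Leu-CAA, Val-CAC, Thr-CGT and Cys-GCA. Some had naive means under the RPM of 3 reads in every naive library, among them Thr-AGT-6-1 (0), His-GTG-1-1 (0.878) and Lys-CTT-1-1 (1.355). Such entries passed the filter of 10 RPM through the activated libraries, and the sizes of their changes are uncertain. Among the more abundant of them, Gln-CTG-3-1 went from 1008 ± 162 RPM in naive cells to 14844 ± 1733 RPM in 48 h CD62L-low cells, and Gly-GCC-1-1 from 1081 ± 563 to 12521 ± 3644 RPM; these examples were chosen after their values were seen. Entries of the same anticodons outside these 45 differed from each other in 48 h CD62L-low cells, where the median log2 change of all entries was 0.46. Ala-AGC-7-1 had a change of 0.66 (adjusted p = 0.0745), Ala-AGC-4-1 fell (-1.41, adjusted p = 0.00324), Ala-AGC-6-1 (0.19) was at 960 ± 178 RPM in naive cells and 1093 ± 150 RPM in 48 h CD62L-low cells, and Val-AAC-5-1 (0.05) at 2086 ± 309 and 2191 ± 548 RPM, neither called. Setting each library to the same median lowered the median log2 change by 0.63 at 20 h, 0.74 and 0.82 at 48 h (CD62L-high and -low) and 0.41 and 0.78 at 72 h, and relative to that median the calls were 46 higher and 35 lower, 52 and 42, 52 and 52, 41 and 29, and 50 and 41. With TMM factors they were 49 and 33, 52 and 40, 55 and 45, 45 and 27, and 54 and 34. No family or entry called under both a scaling alternative and the deposited scale changed direction. For families, the median shift gave 4 higher and 4 lower in 48 h CD62L-high cells, 5 and 3 in 48 h CD62L-low cells and 1 and 5 in 72 h CD62L-high cells, and TMM gave 4 and 3 in the first and 2 and 3 in the last of these.

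**Figure D2:**
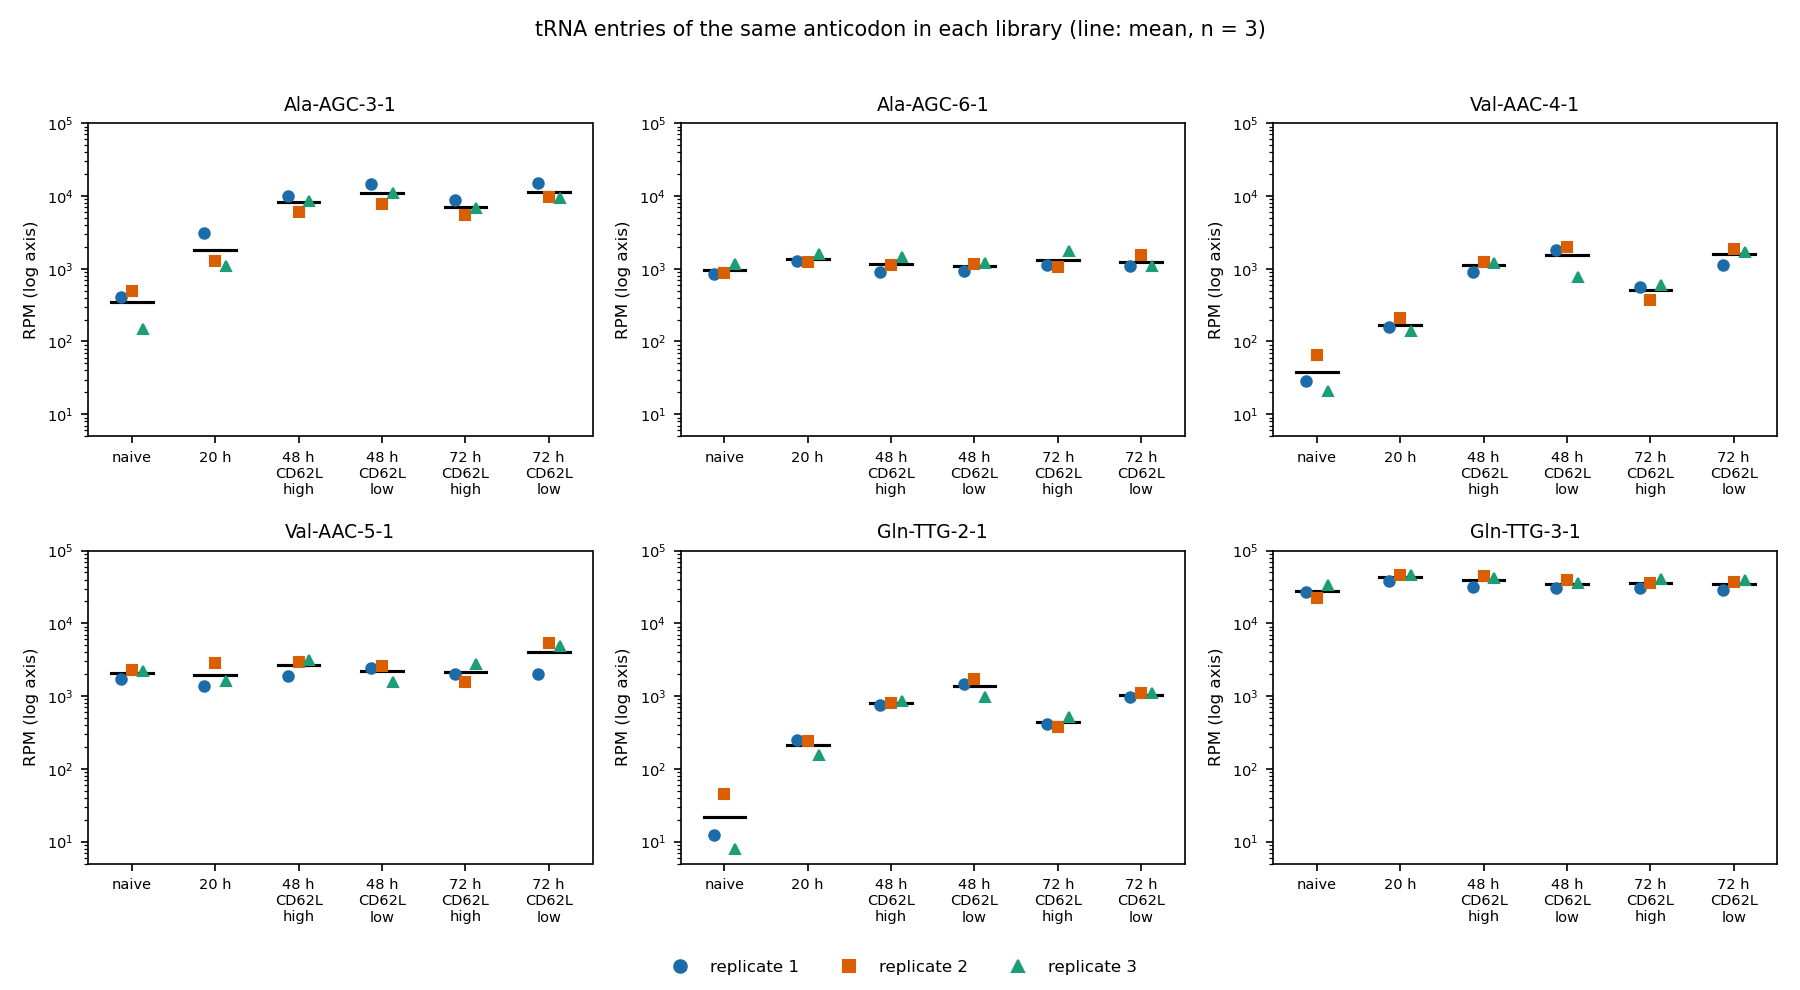
RPM, on a log axis, of 6 tRNA entries in each library by group, with points for libraries and lines for group means (n = 3 each). Ala-AGC-3-1, Val-AAC-4-1 and Gln-TTG-2-1 lie above naive in all 5 activated groups, while Ala-AGC-6-1, Val-AAC-5-1 and Gln-TTG-3-1, which share their anticodons, have naive means of 960, 2086 and 27607 RPM and means of 1093, 2191 and 34970 RPM in 48 h CD62L-low cells.

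Every call above against naive cells had the same sign within the replicate 1 libraries and within the replicate 2 and 3 libraries taken apart. This was checked because the 6 libraries numbered 1 stood apart from the others in every group, on a component holding 54.4% of the residual variance of the families and 35.1% of that of the entries. For items named because their groups did not overlap, an equal sign was fixed in advance. All calls also came from these same libraries, so the equal signs are no independent check on the replicate 1 libraries. Counts without those libraries are given in the closing section. With group in the model, 6 families were higher and 16 lower in them, among them Arg-CCG (1.76) and Arg-CCT (1.85) higher and Arg-ACG (-1.14), Ser-AGA (-1.14) and His-GTG (-0.86) lower. Ala-AGC changed by 2.32 within replicate 1 and by 1.41 within replicates 2 and 3 in 48 h CD62L-low cells, iMet-CAT by -0.83 and -0.78, Phe-GAA by 1.91 and 1.10, Val-AAC by 1.65 and 0.96, and Ser-GGA by 6.48 and 3.12. In 72 h CD62L-high cells the values of Met-CAT were -1.01 and -0.85, and at 20 h those of Ala-TGC were 1.13 and 0.80.

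As a share of all reads, initiator methionine tRNA held 6.22% ± 0.585 in naive cells (SD, n = 3), then 4.24% ± 0.638 at 20 h, 3.82% ± 0.468 and 3.59% ± 0.314 in the CD62L-high and -low cells at 48 h, and 3.37% ± 0.574 and 3.61% ± 0.601 at 72 h. The share differed across the 6 groups (F = 11.5, permutation p = 0.00287, adjusted p = 0.0144 over 5 classes). These are the values of the iMet-CAT family as percentages, so this is not separate evidence. The moderated F test of that family over the 48 families did not pass (adjusted p = 0.0549). Each activated group lay below naive with no overlap, for which the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries can give. Families grouped by the first base of the anticodon did not differ detectably across groups. Those starting with A held 6.28% ± 1.38 in naive cells and 7.95% ± 1.18 in 72 h CD62L-low cells (permutation p = 0.404 across the 6 groups), those starting with C 46.6% ± 5.0 and 50.9% ± 6.24 (permutation p = 0.473), with 53.8% ± 1.60 in 48 h CD62L-low cells, which did not overlap naive (exact permutation p = 0.1), those starting with G 18.1% ± 3.62 and 16.6% ± 2.07 (permutation p = 0.749) and those starting with U 17.4% ± 3.25 and 17.6% ± 2.62 (permutation p = 0.522).

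Of the 18 lists of families fixed in advance, those of the small amino acids (alanine, glycine and serine) and of the sulfur amino acids (cysteine and both methionine families) gave the camera calls. Of the 11 small amino acid families, 2, 3, 3, 1 and 2 rose in the 5 comparisons with naive cells in order of time, CD62L-high first, and none fell; adjusted over the list alone it was 2, 3, 3, 2 and 3. The risers were Ser-GGA, Ala-AGC and Ala-TGC, and no glycine family was called. The median log2 changes of the list were 0.21, 0.30, 0.36, 0.24 and 0.14, below its means of 0.63, 0.53, 0.73, 0.35 and 0.60, and Ser-GGA, whose naive level lies near the RPM of 3 reads, had the highest change in each. By the means the list lay 0.66, 0.58, 0.78, 0.55 and 0.56 above all other families on the log2 scale, with camera adjusted p = 0.0739, 0.149, 0.0651, 0.0221 and 0.197. The call in 72 h CD62L-high cells was lost with an estimated correlation (adjusted p = 0.0821) and without 72 h CD62L-high replicate 2. Of the 3 sulfur families, 0, 1, 1, 2 and 1 fell, and adjusted over the list alone 1, 2, 1, 2 and 1; the list lay 0.79, 0.72, 0.74, 0.81 and 0.71 below the others in log2 change (differences of -0.79, -0.72, -0.74, -0.81 and -0.71), with adjusted p = 0.0335, 0.149, 0.255, 0.0221 and 0.197. Neither sulfur call held with an estimated correlation (adjusted p = 0.145 at 20 h and 0.0821 in 72 h CD62L-high cells), and that at 20 h was also lost without naive replicate 2. As a test of movement in 1 direction without regard to other families, fry gave adjusted p = 0.0242, 0.0278, 0.00440, 0.112 and 0.0283 for the small and 0.0242, 0.0278, 0.0253, 0.00104 and 0.0599 for the sulfur amino acids.

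The other 16 lists had no camera call in any comparison. The families read through inosine had 2 of 8 members higher in 48 h CD62L-low cells (Ala-AGC and Val-AAC, with Leu-AAG at -0.39 and Thr-AGT at -0.27 uncalled; camera adjusted p = 0.868). In the same comparison, 2 of 9 families starting with G rose (Ser-GGA and Phe-GAA, adjusted p = 0.897), 0 of 15 starting with C (Leu-CAA 0.79, adjusted p = 0.897; fry adjusted p = 0.0253) and 1 of 14 starting with U (Ala-TGC, adjusted p = 0.897), and adjusted over the list alone these 4 counts were the same. Groups defined by modification had no riser: 0 of 5 families with Elongator-dependent uridines (Glu-TTC -0.88, Gln-TTG 0.22; adjusted p = 0.897), 0 of 4 with queuosine (Asn-GTT -0.47; adjusted p = 0.897), 0 of 13 with t6A beside the anticodon (iMet-CAT fell; adjusted p = 0.628), 0 of 4 with i6A (SeC-TCA -1.10; adjusted p = 0.933) and 0 of 9 with m3C (Thr-TGT -0.58; adjusted p = 0.974). Of the 11 families with a long variable arm Ser-GGA rose (adjusted p = 0.897), and so did Val-AAC of the 10 branched-chain families (adjusted p = 0.897; 0 adjusted over the list alone) and Phe-GAA of the 3 aromatic families (adjusted p = 0.897). None of the 7 positively charged (Lys-CTT 0.37; adjusted p = 0.897) or 3 negatively charged families (Glu-TTC -0.88; adjusted p = 0.868) was called. The 23 families best matched to codons ending in A or U had 3 risers and the 25 matched to G or C 2 risers and 1 fall (adjusted p = 0.897 each). Over the other 4 comparisons with naive cells the lowest adjusted p among these 16 lists was 0.132, for t6A in 72 h CD62L-high cells, where 2 of its 13 families fell (3 adjusted over the list alone). Median and mean differed in sign in 48 h CD62L-low cells for the families starting with G (-0.08 and 0.46), those starting with U (0.01 and -0.06), the Elongator (0.03 and -0.09), i6A (0.19 and -0.06), branched-chain (-0.06 and 0.02) and aromatic (-0.08 and 0.32) lists. They also differed at 20 h for the i6A, m3C, branched-chain and aromatic lists, in 48 h CD62L-high cells for the lists starting with C, Elongator, m3C, aromatic and both codon endings, in 72 h CD62L-high cells for the inosine list and in 72 h CD62L-low cells for the aromatic list. Adjusted over the list alone, counts changed for inosine in 48 h CD62L-high cells (1 to 2 higher), t6A there (1 to 0 lower) and the A- or U-ending codons in 72 h CD62L-low cells (2 to 3 higher).

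The comparison of 48 h with 20 h, averaged over the CD62L fractions, asks what changed as activation went on, and the gate changed with it, since the 20 h cells were not split. Ala-AGC rose 2.19-fold (log2 change 1.13, SE 0.22, adjusted p = 0.00470), from 6473 ± 1107 RPM at 20 h, and was the 1 family called; the values within replicate 1 and within replicates 2 and 3 were 1.09 and 1.15. iMet-CAT (-0.19), Met-CAT (0.37), Phe-GAA (0.04), Lys-TTT (-0.33) and SeC-TCA (-0.10) did not pass. Of the entries 22 rose and 4 fell. Val-AAC-4-1 went from 170 ± 38.6 RPM to 1112 ± 187 in CD62L-high and 1537 ± 667 RPM in CD62L-low cells (log2 change 2.89), and Val-AAC-2-1 (2.79), Met-CAT-4-1 (2.74), Ala-AGC-3-1 (2.52) and Thr-CGT-3-1 (2.41) rose with it. Gly-GCC-2-1, at 45767 ± 10480 RPM at 20 h, fell by 2.84 to 4567 ± 1116 and 11012 ± 9138 RPM, while the Gly-GCC family was not called (-0.55, adjusted p = 0.722). Arg-TCG-2-1 (-1.59), Thr-TGT-2-1 (-1.11) and Tyr-GTA-4-1 (-0.90) fell too, the last a call lost without any of 12 single libraries (highest adjusted p = 0.184), and that of Thr-TGT-2-1 without 20 h replicate 1 or 2 or 48 h CD62L-high replicate 2 (highest adjusted p = 0.132). The call on Ala-AGC was lost when the 6 replicate 1 libraries were left out, and the split of entry calls became 19 higher and 11 lower with the median shift and 20 and 9 with TMM.

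From 48 h to 72 h, again averaged over the fractions, 1 family changed: Phe-GAA fell by 1.24 (0.424-fold, SE 0.30, adjusted p = 0.0425), with -1.48 within replicate 1 and -1.12 within replicates 2 and 3. This call was lost on leaving out any of 11 of the 18 libraries (highest adjusted p = 0.151). iMet-CAT (-0.10), Met-CAT (-0.36), Lys-TTT (-0.17) and SeC-TCA (0.55) did not pass. Of the 148 entries 16 fell and 0 rose. Among them were all 3 Phe-GAA entries tested, Lys-TTT-2-1 (-1.77), Gly-CCC-2-1 (-1.61, from 3251 to 1220 ± 309 RPM in CD62L-low and from 1997 ± 528 to 584 ± 172 RPM in CD62L-high cells) and Thr-CGT-3-1 (-1.39). Phe-GAA-2-1 and Phe-GAA-3-1 changed by -1.75 and -1.65. Each of these named calls was lost without 1 or another of at least 5 single libraries, with a highest adjusted p = 0.123. Without 48 h CD62L-high replicate 2 the entries called were 6. With the libraries shifted to 1 median, 12 entries fell and 3 rose, and with TMM 9 fell and 2 rose.

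The comparison of CD62L-low with CD62L-high cells, averaged over 48 h and 72 h, sets the cells labelled effector against those labelled memory. With limma, 0 of 48 families passed, and 6 had an unadjusted p under 0.05; with a term for the replicate 1 libraries 2 families and 8 entries were higher. Phe-GAA (2.27-fold higher in CD62L-low cells, log2 difference 1.18, SE 0.30) came nearest at adjusted p = 0.0626, and passed after TMM scaling (1.09, adjusted p = 0.0148) and the median shift (1.09), and without 72 h CD62L-low replicate 1. Leaving out that library or naive replicate 1 gave 2 families, and leaving out naive replicate 2 gave 1. Its values within replicate 1 and within replicates 2 and 3 were 1.17 and 1.19. Other families named in every comparison did not pass: Met-CAT 0.43 (adjusted p = 0.311), Lys-TTT 0.93 (adjusted p = 0.369), SeC-TCA -0.63 (adjusted p = 0.369) and iMet-CAT 0.01 (adjusted p = 0.977). Of the entries 1 rose, Lys-TTT-3-1 (1.86, adjusted p = 0.00599), which lies below the level for named entries with a mean of 20.6 RPM and was chosen after its values were seen; without naive replicate 2, 19 rose and 1 fell. Counts adjusted over the list alone were 2 higher for the families starting with G and for those matched to G- or C-ending codons, and 1 each for the long variable arm, small and aromatic lists. None of the 18 lists was called (lowest camera adjusted p = 0.360, for the long variable arm and the aromatic amino acids; lowest fry adjusted p = 0.490). The long variable arm list had a median of -0.02 and a mean of 0.06, and the positively charged list -0.03 and 0.15.

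At 48 h alone no family and no entry separated the CD62L fractions by limma, with 0 families and 2 entries at an unadjusted p under 0.05. At 72 h, 3 families were higher in CD62L-low cells. Phe-GAA was at 2277 ± 866 RPM in CD62L-low and 626 ± 196 RPM in CD62L-high cells (3.54-fold, log2 difference 1.82, SE 0.43, adjusted p = 0.0298), Met-CAT at 9892 ± 1468 and 5350 ± 1047 RPM (1.86-fold, adjusted p = 0.0363), and Ser-GGA at 176 ± 132 and 21 ± 9.08 RPM (log2 difference 2.66, adjusted p = 0.0416). Within replicate 1 and within replicates 2 and 3 the differences were 1.54 and 1.97 for Phe-GAA, 0.68 and 1.01 for Met-CAT and 1.54 and 3.22 for Ser-GGA. The call on Phe-GAA was lost without 72 h CD62L-high replicate 1 or 2 or CD62L-low replicate 2 or 3 (highest adjusted p = 0.205), that on Met-CAT for 7 of the 18 libraries (highest adjusted p = 0.205) and that on Ser-GGA for 10 of them (highest adjusted p = 0.318). The difference of Ser-GGA lay between 2.06 and 3.52 over the libraries left out in turn. TMM ended the calls on Met-CAT (0.71, adjusted p = 0.0873) and Ser-GGA (2.48, adjusted p = 0.0626). Lys-TTT (1.49), SeC-TCA (-0.52) and iMet-CAT (0.10) did not pass. The 3 entries called were Phe-GAA-1-1 (1.79, adjusted p = 0.0450), Met-CAT-3-1 (1.25, adjusted p = 0.0183) and Lys-TTT-3-1 (2.21, adjusted p = 0.0183), and with limma 0 passed after TMM scaling, where 21 had an unadjusted p under 0.05, while 18 passed without naive replicate 2. More than these 3 also passed with a term for the replicate 1 libraries or for the replicate number, as given in the closing section. The call on Phe-GAA-1-1 was lost for 11 of the 18 libraries (highest adjusted p = 0.236) and that on Met-CAT-3-1 without 72 h CD62L-high replicate 1 or 2 or CD62L-low replicate 3 (highest adjusted p = 0.136). At 72 h the median shift lowered the median log2 difference of the entries by 0.37. A test of whether the difference between fractions itself differed between 72 h and 48 h called 0 families and 0 entries by limma, with 1 family and 5 entries at an unadjusted p under 0.05. For Phe-GAA, Met-CAT and Lys-TTT that difference was 1.28, 0.93 and 1.11 (adjusted p = 0.701, 0.616 and 0.928), so the fractions were not shown to differ more at 72 h than at 48 h.

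Across all 6 groups together, the moderated F test called 5 families, Ala-AGC (adjusted p = 0.000500), Ser-GGA (adjusted p = 0.00156), Phe-GAA (adjusted p = 0.00714), Val-AAC (adjusted p = 0.0191) and Ala-TGC (adjusted p = 0.0238), and 71 entries. Without naive replicate 1, or without 20 h replicate 3, the families called were 3.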

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

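The term for the replicate 1 libraries, leaving those libraries out, thinning and summing pairs were chosen only after the results were seen. Families and entries called both in the reported fit and under a pseudocount, filter, scaling, moderation, replicate or compared-groups setting kept their sign; this was not counted for thinning, summed pairs or single libraries left out. Of the counts under these alternatives, 236 stayed within 1.5 times the value reported and 62 moved further; robust moderation kept all of its counts within that range. Outside the counts, 8 list tests became calls and 14 were lost, and 11 named values became calls and 18 were lost; with single libraries left out, 2 list tests and 56 named values were lost and 7 named values became calls. For the changes below the cause was not tested. The planned edgeR and DESeq2 alternatives were not run: the values were whole multiples of a step, but fewer of them were low than was required for a count test. As a check of pairing, the deviations of libraries with equal numbers correlated over 0.1 by families in 15 of 15 pairs for replicate 1 (median r = 0.76) and replicate 3 (0.551) and in 8 of 15 for replicate 2 (0.116), and by entries in 15, 8 and 8 of 15. Since not every pair did and the labels do not state it, the numbers were not taken as pairs. This does not show that the libraries are unpaired. If the numbers mark pools, the reported fit leaves a pool difference in the spread. With the replicate number as a term, given below, more families and entries were called between the CD62L fractions over both times. The best correlate outside a library's own group had its number for 12 of 18 libraries by families and 10 of 18 by entries. Most libraries thus resembled another of their own number, and the rate for unrelated libraries was not worked out. The unpaired fit is a choice that these values do not settle.

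Counts by limma that moved by more than 1.5 times follow. TMM factors gave 1 family at 20 h, 7 in 48 h CD62L-high, 5 in 72 h CD62L-high, 2 for 48 h against 20 h, 1 between CD62L fractions and 1 at 72 h, and 0 entries at 72 h. The median shift gave 1, 8, 6, 2 and 2 families for the first 5 of these. The replicate 1 term gave 4 families at 20 h, 6 in 72 h CD62L-high, 2 for 48 h against 20 h and 2 between fractions, and 26 entries for 72 h against 48 h, 15 between fractions at 72 h and 8 over both times. The replicate number as a term gave the same 4 family counts, 4, 6, 2 and 2, with 13 and 11 entries between fractions. The compared groups alone gave 1 family at 20 h, 0 in 48 h CD62L-high, 2 in 48 h CD62L-low, 0 in 72 h CD62L-high, 0 between fractions at 72 h and 1 over both times, and 32 entries in 72 h CD62L-high and 13 between fractions. A filter at 100 RPM gave 7 entries for 72 h against 48 h, 1 between fractions at 72 h and 0 over both times; no filter gave 8, 1 and 2, and 0 families for 72 h against 48 h. Without the replicate 1 libraries there was 1 family at 20 h, 1 in 48 h CD62L-high, 2 in 48 h CD62L-low, 0 in 72 h CD62L-high, 0 for 48 h against 20 h, 0 for 72 h against 48 h, 2 between fractions and 1 for the difference between times, and 4, 0 and 0 entries for 72 h against 48 h and between fractions at 72 h and over both times. Thinning gave 1 family between fractions, and 8, 0 and 0 entries. Summed pairs gave 8 and 3 entries between fractions at 72 h and over both times, a pseudocount of 0.1 gave 1 and 0, and a pseudocount of 10 gave 12 and 11, with 1 at 48 h.

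With each library left out in turn, families ranged from 1 to 4 at 20 h, 1 to 5 and 3 to 8 in CD62L-high and -low cells at 48 h, 1 to 4 and 3 to 5 at 72 h, 1 to 2 for 48 h against 20 h, 0 to 1 for 72 h against 48 h, 0 to 2 between fractions, 0 to 4 at 72 h and 3 to 6 across groups; they were 0 at 48 h and for the difference between times. Entries ranged from 58 to 72, 62 to 74, 74 to 81, 47 to 63, 61 to 72, 18 to 32, 6 to 22, 1 to 20, 0 to 18 and 59 to 78 in the same order. At this depth, items near the floor of 3 reads have uncertain changes, Ser-GGA among them.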

Other observations

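The tests of scaling, of reads passed on within an anticodon or amino acid, of scores, of the pairs with opposite values and of the minor members against the major ones were chosen only after the results were seen. Entries that held a small share of their anticodon family in naive cells took a larger share of all reads in the activated groups. Shares within a family in the activated groups were not worked out, and a rise of a whole family, such as Ala-AGC, would also raise these values. The 72 entries holding under 10% of their family in naive replicate 1 together took 4.17% and 2.57% of all reads in naive replicates 2 and 3, which were not used to pick them, 11.2% ± 1.44 at 20 h (SD, n = 3), 10.2% ± 1.14 and 13.2% ± 0.729 in CD62L-high and -low cells at 48 h, and 7.13% ± 0.966 and 9.29% ± 1.04 at 72 h. Gln-CTG-3-1 and Leu-CAA-4-1 were among the rising entries. Alanine tRNA as a whole took 1.19% of reads in naive cells and was 1.71-fold and 2.13-fold higher at 48 h (CD62L-high, adjusted p = 0.0483; CD62L-low, adjusted p = 0.00547) and 2.04-fold higher in 72 h CD62L-low cells. It was not called at 20 h (1.36-fold, adjusted p = 0.340) or in 72 h CD62L-high cells (1.65-fold, adjusted p = 0.0541), and valine tRNA was called in none of the 5 comparisons (0.810-fold to 1.23-fold).

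The first pattern is the 45 entries higher in all 5 activated groups. Depth and scaling do not account for it as a whole: 42 were still higher in all 5 after thinning to the lowest depth, 37 after the median shift and 41 with TMM. The thinning took the multiples of the step as reads, so its result holds only if they are. With the 7 pairs summed, 40 were, not counting an entry merged into its partner. The sums of Ala-AGC-1-1 with Ala-AGC-5-1, Ala-AGC-7-1 with Ala-AGC-3-1 and Gln-CTG-4-1 with Gln-CTG-1-1 were called higher in 5 of 5 comparisons (1.75 to 5.12). Those of the Tyr-GTA, Gly-CCC, Ala-TGC and Ala-CGC pairs were called in 0 of 5. Exchange with entries outside these pairs is not covered. Reads passed on from other entries of the same anticodon stay open, since the median loss of the others over the gain was 0.624 (95% interval -0.367 to 2.22 over 28 families). For alanine this is argued against at 48 h and 72 h, where the change of its total lay above 2 SE in all 4 comparisons, but not at 20 h (0.4451); for valine the lowest total change was -0.3032, which leaves it open. Stray reads on poorly scoring entries also stay open, with a median score 1.2 higher in the 45 (76.7 against 75.5, permutation p = 0.41).

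The second pattern is a set of entry pairs whose values differed in opposite directions, between groups or between the libraries of a group. For Tyr-GTA-2-1 and Tyr-GTA-3-1 the spread of the sum within groups was 0.15 of the spread of their ratio. The sum was called in 0 of 5 comparisons by limma, as reads shared between near-identical copies would give. A low ratio was also a condition for summing a pair, so it is no separate support. It does not mark shared reads by itself: Asn-GTT-1-1 and Asn-GTT-3-1, which varied together within groups (r = 0.56), had a ratio of 0.201. The ratio was 0.318 for Gly-GCC-2-1 and Gly-GCC-4-1 and 0.075 for Ala-TGC-2-1 and Ala-TGC-3-1, both under 0.5. Whether the sum was called less often than its members was not tested for the Gly-GCC pair and could not be judged for the Ala-TGC pair. Only pairs with a within-group r under -0.5 were summed, and that of the Gly-GCC pair was -0.324. The Gly-GCC family, which also holds Gly-GCC-1-1, was called in 0 of 5 comparisons with naive cells. Neither member of the Ala-TGC pair was called, so its sum could not be called less often. The opposite values of the Ala-TGC pair were between libraries of the same group (r = -0.621); against naive cells both changes were negative in 4 of 5 comparisons, and neither entry was called in any. A difference in expression between the copies was not tested against this.

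The third pattern is the rise of minor members against major ones. Over 40 families, the median log2 change was 2.25 for 72 minor and -0.23 for 68 major members, a difference of 2.48. Permuting the minor and major labels over entries gave permutation p = 1e-05, the smallest that 100000 resamples give. The labels were set by shares within a family, so entries of a family are not independent and that p may be too small. Libraries were not permuted, so the p measures no spread between libraries or pools of mice. Picking minor members in a replicate 1 library of each activated group instead gave a naive-minus-activated difference from -1.24 to -2.00, so low entries did not simply move up away from the group they were picked in. Entries low in both kinds of pick were not counted, so this is no separate evidence of the rise. In each pick the group picked in lacked its replicate 1 library, while the groups set against it kept theirs. Shared reads between entries remain open, as in the first pattern (0.624), and so does activation itself, which was not tested apart from them.

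Whether other groupings of the libraries give as many calls was counted for each comparison. For a single activated group against naive cells, and for the fractions at 1 time, the 10 possible splits are too few for a share under 0.05. For families the real split and the highest other gave 2 and 0 at 20 h (1 of 10 splits as large), 4 and 0 in 48 h CD62L-high, 6 and 2 in 48 h CD62L-low, 3 and 0 in 72 h CD62L-high, 4 and 5 in 72 h CD62L-low (2 of 10), 0 and 0 between fractions at 48 h (10 of 10) and 3 and 0 at 72 h. The split with 5 set naive replicates 1 and 3 and 72 h CD62L-low replicate 1 against the rest. For entries they were 68 and 0, 68 and 0, 79 and 1, 62 and 0, 66 and 0, 0 and 0, and 3 and 0. Fewer than 5 in 100 splits gave as many calls for 72 h against 48 h (families, 4 of 100 splits, 1 and 9; entries, 1 of 100, 16 and 9), 48 h against 20 h (4 of 84, 1 and 4; 1 of 84, 26 and 17) and all 6 groups (3 of 100, 5 and 5; 1 of 100, 71 and 61). For entries between fractions over both times 8 of 100 did so (1 and 3). Where the real split gave 0 calls by limma every split gives as many, so the share says nothing: this holds for families between fractions over both times (100 of 100, 0 and 3), for the difference between times (100 of 100, 0 and 6 for families, 0 and 4 for entries) and for the fractions at 48 h. A split with 9 families, several times the real 1, points to a structure of the libraries; which one was not tested.

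Some values belong to single libraries. Naive replicate 2 had Lys-TTT at 18907 RPM against 2659 and 3082 RPM in the other naive libraries.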
